A study of Homo sapiens with 9 samples.

How the data were processed

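RNA was measured in 9 libraries of MDA-MB-231 cells, 3 given DMSO, 3 given 10 nM PdB for 16 h and 3 collected 24 h after PdB. Libraries were made from polyadenylated RNA with the Universal Plus mRNA-Seq kit with NuQuant, per the labels. The authors deposited a table of whole-number read counts for 60708 genes in the 9 libraries, not normalised. Per the submitters' processing notes, fastp 0.23.2, STAR 2.7.9a, Picard, featureCounts 2.0.3 and DESeq2 1.30.0 were used with the hg38 genome. Their roles and settings, the annotation release, the use of strand, and the treatment of duplicates and of reads that map to several places are not given in the sources used here. Reads from a gene and an overlapping or antisense gene, or from near-identical copies such as 7SL and U3 RNA genes, processed pseudogenes, SLX1A, HSPA1A and HSPA1B and histone genes, may therefore be counted together, and values of such genes are uncertain. A symbol was found for 60463 gene IDs, and 58426 matched the GENCODE 29 annotation of GRCh38, from which coordinates, gene types and introns were taken.

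Total counts per library ranged from 56389689 to 67047079. A value of 0 in DMSO was read against a floor of 3 counts per library, 0.0449 CPM on average, which covers counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries agreed within counting noise: the chi-square per degree of freedom of library pairs within groups lay between 4.30 and 19.9. No library was therefore taken for a second deposit of another, which does not show that they came from separate cultures. Groups shared replicate numbers in the labels. The numbers were not used to pair samples.

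The 3 comparisons were PdB against DMSO, recovery against DMSO and recovery against PdB. Counts were filtered with filterByExpr, leaving 20812 genes, scaled by TMM (mean factor 1.03 in DMSO, 0.898 in PdB and 1.08 at recovery) and tested two-sided with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with all 9 libraries in the fit and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.111. CPM are TMM-scaled. Genes changed under PdB were called returned, persistent, overshooting or undetermined from the 3 tests. The 31 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over all 93 tests. No list call held with an estimated correlation, where adjusted p ran from 0.30 to 0.98. The loss of a call there cannot be put down to correlation between genes alone. The drug transport and chemotherapy list had an estimated correlation of -0.021, below the preset value. Its camera adjusted p at recovery against DMSO still went from 0.048 to 0.34. The lists were SF3B and U2 snRNP, other core spliceosome, SR proteins and kinases, hnRNP proteins, snoRNA hosts, nonsense-mediated decay, single-exon genes, replication-dependent histones, homologous recombination, Fanconi anaemia, end joining, excision and mismatch repair, DNA damage checkpoint, R-loop resolution, DNA replication, G2 and mitosis, BCL2 family, unfolded protein and integrated stress response, heat shock, immediate early, NF-kB and cytokines, interferon-stimulated, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded, mesenchymal, luminal and leukocyte markers, and drug transport and chemotherapy response. Some genes stand in more than 1 list. A further list and a few genes are not reported here. Genes were also grouped by the introns of their longest annotated transcript.

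The lists, tests, alternatives and the rule for naming genes were chosen before the data were examined. Named genes were, per comparison, the 8 largest rises and falls with a mean of at least 100 counts, complete separation of the replicates and a symbol that is not a clone or locus name; per list and comparison, the largest rise and fall; 35 genes fixed in advance; and the 6 largest rises and falls of the persistent class. The alternatives were RLE, upper-quartile and library-total scaling, no filter, a mean of at least 50 counts, FDR 0.01, DESeq2 1.42.0, a test against a 2-fold change, only the 6 libraries compared, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. The scripts were tested on simulated data with 200 changed genes among 20812, taken above a minimum level in DMSO and moved up or down at random. Far more genes changed in the real data, so the shares below need not hold there. For PdB against DMSO, 74.6% of genes changed by 1.5-fold, 84.3% by 2-fold and 100% by 4-fold were recovered, with 5.46% false calls. For recovery against DMSO the shares were 72.1%, 87.9% and 100% with 5.38% false, and for recovery against PdB 71.2%, 92.8% and 100% with 5.85% false. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.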

Results

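To follow gene expression during and after a block of splicing, RNA was measured in MDA-MB-231, a human cell line derived from a triple-negative breast cancer, a tumour type that lacks the oestrogen and progesterone receptors and amplified HER2. The inhibitor was pladienolide B (PdB), a macrolide that binds the SF3B1 complex of the U2 snRNP, the particle that recognises the intron branch point. The 9 libraries fell into 3 groups of 3: vehicle (DMSO), 10 nM PdB for 16 h, and PdB followed by 24 h of recovery. The series concerns brief loss of splicing activity as a route to DNA damage and drug sensitivity in tumour cells that are still able to perform homologous recombination. The DMSO libraries held 66111833, 61734210 and 67047079 counts, the PdB libraries 64022867, 63344840 and 56389689 counts and the recovery libraries 57799058, 58262409 and 62020549 counts. At least 10 counts were found for 19258 ± 219 genes in DMSO, 19177 ± 30.8 in PdB and 20126 ± 181 at recovery (mean ± SD, n = 3). Mitochondrial genes held 5.21% ± 0.484 of the counts in DMSO, 7.60% ± 0.866 in PdB and 8.12% ± 0.0866 at recovery. Libraries of the same group correlated across genes with r between 0.975 and 0.988, and libraries of different groups with r between 0.900 and 0.945. Levels are given as mean CPM (the counts of a gene scaled to the size of its library) ± SD and log2 changes are ± SE, with n = 3 libraries per group throughout. Adjusted p-values are those of edgeR for single genes and of camera for gene lists. The labels do not say that the replicates were separate cultures, so the p-values of edgeR measure only the spread between these samples, which may be technical. Camera with the preset correlation compares the members of a list with other genes, so its p-values rest on the spread between genes. They do not measure how a list varies between replicates.

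The comparison of PdB with DMSO asked which genes differed after 16 h of treatment. Genes of the dividing cell were lower. Of 36 genes of G2 and mitosis, 3 rose and 32 fell (median log2 change -1.54, camera adjusted p = 1.2e-08, adjusted p = 0.34 with an estimated correlation). TOP2A, the topoisomerase that separates replicated chromosomes (ENSG00000131747.15, chromosome 17, 40388516 to 40417950), fell from 686 ± 33.0 to 35.2 ± 0.12 CPM, a log2 change of -4.28 ± 0.052 (adjusted p = 1.3e-19). KIF2C, a kinesin that shortens microtubules at kinetochores, fell from 146 ± 3.4 to 8.91 ± 1.3 CPM. CDK1, the kinase that starts mitosis, rose from 133 ± 3.4 to 180.2 ± 18.7 CPM. CCNB1, its partner cyclin, fell from 236 ± 9.7 to 189 ± 12.5 CPM. Of 45 DNA replication genes, 4 rose and 38 fell (median log2 change -1.17, camera adjusted p = 1.0e-07, adjusted p = 0.34 with an estimated correlation). POLA2, a subunit of DNA polymerase alpha, fell from 30.6 ± 2.1 to 2.43 ± 0.69 CPM, a log2 change of -3.66 ± 0.15. CCNE2, a cyclin of S-phase entry, fell from 42.9 ± 0.67 to 11.5 ± 1.9 CPM (log2 change -1.90 ± 0.094, adjusted p = 2.1e-12). Among the transcription factors that drive S-phase genes, E2F2 rose from 16.6 ± 1.2 to 48.2 ± 4.9 CPM, while E2F1 fell from 121 ± 5.9 to 38.3 ± 0.79 CPM (log2 change -1.65 ± 0.056).

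Many DNA repair genes were lower under PdB. Of 44 homologous recombination genes, 7 rose and 30 fell (median log2 change -0.86, camera adjusted p = 0.010, adjusted p = 0.34 with an estimated correlation). BRCA1 (ENSG00000012048.23, chromosome 17, 43044295 to 43170245), a tumour suppressor that directs resection of DNA ends, fell from 57.2 ± 2.2 to 8.64 ± 1.4 CPM (log2 change -2.72 ± 0.094, adjusted p = 1.3e-14). BRCA2, a mediator of strand exchange, fell, with a log2 change of -1.03 ± 0.12. PALB2, which links it to BRCA1, did not pass the test (-0.082 ± 0.085, adjusted p = 0.41). BARD1, the partner of BRCA1, changed by -0.21 ± 0.069 (adjusted p = 0.011), a call that ended with RLE factors (adjusted p = 0.15). RNF8, a ubiquitin ligase at DNA breaks, rose from 50.9 ± 1.4 to 152 ± 1.2 CPM. Of 38 genes of excision and mismatch repair, 5 rose and 28 fell (median log2 change -0.84, camera adjusted p = 0.00073, adjusted p = 0.34 with an estimated correlation), from NEIL3, a DNA glycosylase, at -2.99 ± 0.15 to APEX1, the abasic site endonuclease, at 1.15 ± 0.056. Of 24 DNA damage checkpoint genes, 6 rose and 16 fell (median log2 change -0.63, camera adjusted p = 0.027, adjusted p = 0.45 with an estimated correlation), and this call ended among genes with a mean of at least 50 counts (adjusted p = 0.077). CDC25C, the phosphatase that activates CDK1, fell from 19.1 ± 1.0 to 3.34 ± 0.20 CPM. The kinases ATM and ATR, which signal DNA breaks and stalled forks, changed by -0.65 ± 0.083 and -0.57 ± 0.086. CHEK1, the kinase downstream of ATR, changed by 0.34 ± 0.056. PPM1D, a phosphatase that ends the signal, rose by 1.39 ± 0.078.

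Further repair lists held members in both directions without a list call. Of 22 Fanconi anaemia genes, which act on DNA crosslinks, 5 rose and 15 fell (camera adjusted p = 0.085). FANCD2, the subunit ubiquitylated in that pathway, changed by -1.67 ± 0.096 and FANCL, the ligase that modifies it, by -3.83 ± 0.16. Of 24 genes that resolve R-loops, the RNA:DNA hybrids that form behind RNA polymerase, 7 rose and 16 fell (camera adjusted p = 0.15). In the enzyme that cuts the RNA of such hybrids, RNASEH2A changed by -0.89 ± 0.061 and RNASEH2B by -1.75 ± 0.12. Of 18 end joining genes, 10 rose and 7 fell (camera adjusted p = 0.58), or 6 and 8 with library totals. Their median log2 change was 0.22 (0.017 with library totals), their mean -0.076 and the direction of the test up. TP53BP1, which restrains resection, fell from 46.1 ± 1.1 to 10.8 ± 1.5 CPM.

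**Figure D1:**
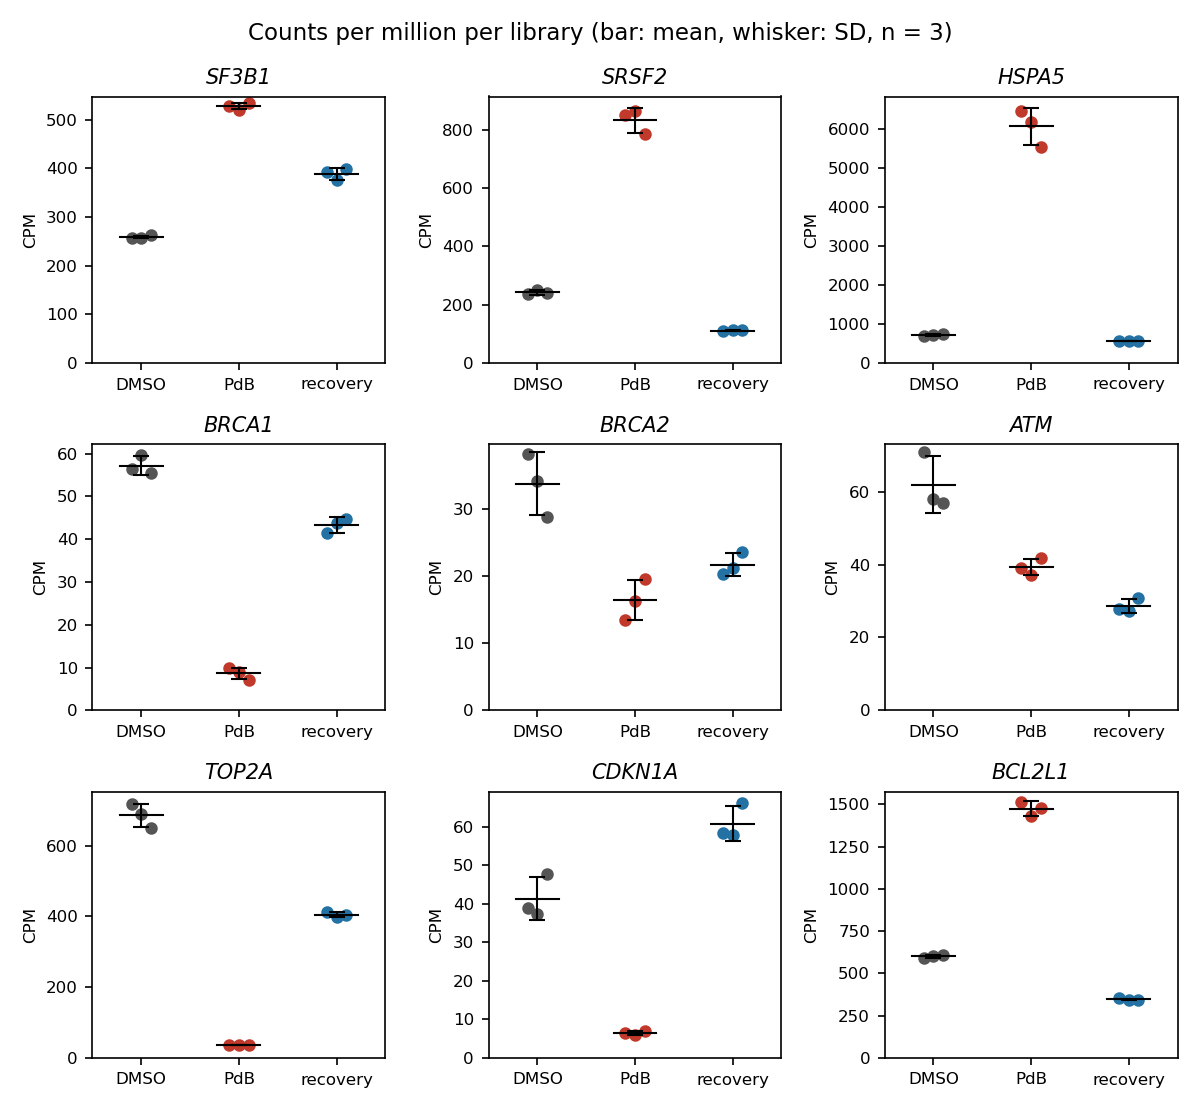
CPM of 9 named genes on linear axes that start at 0, with each library as a point, the group mean as a bar and the SD of its 3 libraries as a whisker. BRCA1 lay at 57.2 CPM in DMSO, 8.64 in PdB and 43.3 at recovery, and HSPA5 at 716, 6053 and 559 CPM.

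SR protein, stress response, immediate early and ribosomal protein genes rose as lists, while the other splicing lists were not called. SF3B1 (ENSG00000115524.17, chromosome 2, 197389784 to 197435091), a subunit of the complex bound by PdB, rose from 259 ± 2.9 to 528 ± 6.3 CPM (log2 change 1.03 ± 0.042, adjusted p = 1.4e-13). PHF5A, which lines the same binding pocket, rose by 1.20 ± 0.086, and SF3B3, a scaffold of the complex, fell with a log2 change of -0.85 ± 0.046. Among the 20 genes of the SF3B complex and the U2 snRNP, 11 rose and 7 fell, without a list call (camera adjusted p = 0.17). Of 23 SR proteins and their kinases, which select exons, 17 rose and 4 fell (median log2 change 1.17, camera adjusted p = 0.00038, adjusted p = 0.34 with an estimated correlation). SRSF2 rose from 242 ± 8.1 to 833 ± 42.7 CPM and SON, a large SR-like protein of nuclear speckles, rose from 301 ± 12.2 to 1350.0 ± 184 CPM. Of 26 genes of the unfolded protein and integrated stress responses, 17 rose and 5 fell (median log2 change 0.82, camera adjusted p = 0.0021, adjusted p = 0.34 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum (ENSG00000044574.9, chromosome 9, 125234853 to 125241330), rose from 716 ± 20.9 to 6053 ± 468 CPM, a log2 change of 3.08 ± 0.052. DNAJB9, its co-chaperone, rose from 8.04 ± 0.12 to 87.7 ± 10.6 CPM. DDIT3 and ATF4, transcription factors of the integrated stress response, changed by 2.31 ± 0.084 and 1.01 ± 0.059. Of 30 immediate early genes, which respond to signals within minutes to hours, 20 rose and 6 fell (median log2 change 1.31, camera adjusted p = 0.00086, adjusted p = 0.34 with an estimated correlation). NR4A2, a nuclear receptor, rose from 2.15 ± 0.41 to 59.5 ± 17.8 CPM, ATF3 rose by 2.12 ± 0.086, MYC rose from 182 ± 4.6 to 492 ± 10.1 CPM and KLF2 fell from 30.6 ± 1.1 to 5.50 ± 0.44 CPM. FOS changed by 1.27 ± 0.14 (adjusted p = 1.9e-07). JUN, a subunit of the AP-1 factor, did not pass the test (log2 change 0.073 ± 0.049, adjusted p = 0.19), and its change was -0.12 with library totals.

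All 78 cytosolic ribosomal protein genes rose (median log2 change 0.74, camera adjusted p = 3.9e-15, adjusted p = 0.58 with an estimated correlation), led by RPL30 at 1.59 ± 0.061. Of 56 nuclear genes of oxidative phosphorylation, 39 rose and 8 fell (median log2 change 0.40, camera adjusted p = 0.00073, adjusted p = 0.70 with an estimated correlation), from UQCRQ of complex III at 1.44 ± 0.064 to SDHA of complex II at -1.47 ± 0.057. All 15 mitochondrially encoded genes rose (median log2 change 0.64, camera adjusted p = 0.00046, adjusted p = 0.58 with an estimated correlation), most of all the large ribosomal RNA MT-RNR2 at 1.66 ± 0.055. Of 22 snoRNA host genes, non-coding transcripts that carry small nucleolar RNAs in their introns, 16 rose and 4 fell (median log2 change 0.68, camera adjusted p = 0.0024, adjusted p = 0.58 with an estimated correlation). SNHG17 rose from 54.8 ± 8.6 to 478 ± 67.3 CPM and GAS5 changed by 0.64 ± 0.067. Directions of these 4 lists were the same under TMM, RLE, upper-quartile and library-total scaling.

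**Figure D2:**
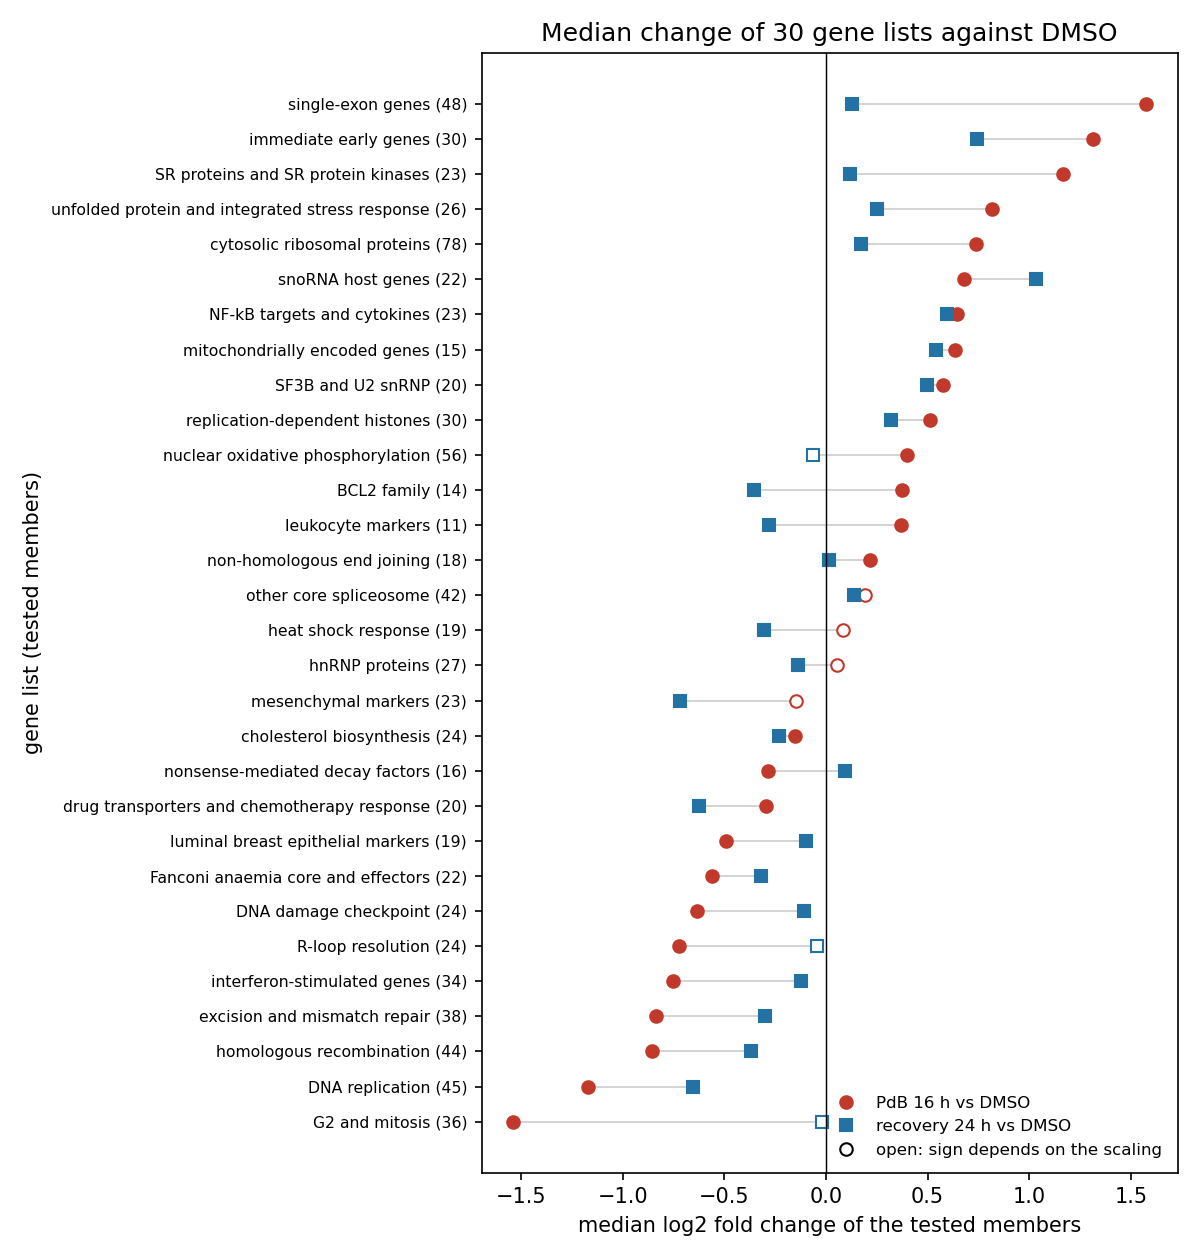
Median log2 change of the tested members of each of 30 gene lists, for PdB against DMSO as circles and recovery against DMSO as squares, with open points where the sign depends on the scaling. The single-exon list lay at 1.57 under PdB and 0.13 at recovery, the DNA replication list at -1.17 and -0.65, and the G2 and mitosis list at -1.54 and -0.020, the last of which was 0.056 with upper-quartile factors.

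The other lists were not called under PdB, with camera adjusted p from 0.085 to 0.91. Of 42 other core spliceosome genes, 23 rose and 15 fell, with PRPF3 at 1.88 ± 0.053 and LSM8 at -2.67 ± 0.085. Of 27 hnRNP genes, 13 rose and 13 fell, and of 16 nonsense-mediated decay factors 4 rose and 9 fell. CDKN1A, an inhibitor of cyclin-dependent kinases, fell from 41.3 ± 5.6 to 6.41 ± 0.48 CPM, and MDM2, a ubiquitin ligase gene, rose by 0.67 ± 0.054. Of 14 BCL2 family genes, 8 rose and 4 fell. The survival gene BCL2L1 rose from 600.1 ± 8.9 to 1474 ± 42.9 CPM and its relative MCL1 changed by 0.76 ± 0.046, while BIK, a pro-apoptotic member, fell from 0.567 ± 0.14 to 0.0354 ± 0.061 CPM. The BIK level in PdB lay below that of 3 counts per library (0.053 CPM in PdB replicate 1). The size of its fall is therefore uncertain. Of 23 NF-kB targets and cytokines, 11 rose and 7 fell, with IL6 at 2.37 ± 0.18, CXCL8 at 1.80 ± 0.19 and PTGS2 at 3.51 ± 0.27. Of 34 interferon-stimulated genes, 7 rose and 20 fell, with IFIT5 at 1.46 ± 0.073 and IFI44L at -2.65 ± 0.86, and IFIT1 changed by 0.55 ± 0.090 (adjusted p = 2.2e-05). Of 24 cholesterol synthesis genes 8 rose and 13 fell (10 and 8 with upper-quartile factors), and of 19 heat shock genes 9 rose and 5 fell. Of 30 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 7 rose and 0 fell. Of 23 mesenchymal markers, 7 rose and 12 fell, with SNAI1 at 2.28 ± 0.23, ITGA5 at -1.79 ± 0.085 and VIM at -0.41 ± 0.044. Of 19 luminal epithelial markers 5 rose and 8 fell, of 11 leukocyte markers 3 rose and 2 fell, and of 20 genes of drug transport and chemotherapy response 7 rose and 10 fell. In the last list SLFN11, which stalls replication forks in cells exposed to DNA-damaging drugs, rose from 0.179 ± 0.062 to 10.4 ± 0.51 CPM. With library totals the medians of the other core spliceosome, hnRNP and heat shock lists were -0.0061, -0.14 and -0.11, and with upper-quartile factors that of the mesenchymal list was 0.0014.

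Single changes were ranked among genes that passed the test with a mean of at least 100 counts, complete separation of the replicates and a symbol that is not a clone or locus name. The largest of these under PdB were rises from very low levels. NXPE2 (ENSG00000204361.10, chromosome 11, 114678386 to 114706933) had no counts in DMSO and 8.37 ± 0.60 CPM in PdB, at least 186-fold higher against a floor of 3 counts per library. RNF225, a gene without introns, rose from 0.0386 ± 0.044 to 16.6 ± 3.8 CPM, CMYA5, a muscle protein gene, from 0.271 ± 0.13 to 55.1 ± 7.2 CPM, and GJC1, a connexin gene, from 0.0533 ± 0.047 to 7.80 ± 2.9 CPM. ZNF233 rose from 0.0393 ± 0.030 to 6.44 ± 1.4 CPM. SNORA68 and SNORD82, small nucleolar RNAs, rose from 0.249 ± 0.18 to 71.4 ± 3.3 CPM and from 0.0256 ± 0.024 to 4.24 ± 1.1 CPM. RN7SL146P rose from 0.0291 ± 0.025 to 8.14 ± 1.1 CPM, but copies of 7SL RNA share reads, so its change is uncertain. The largest falls among the genes ranked were in SYNE3, a nuclear envelope protein gene (ENSG00000176438.13, chromosome 14, 95407266 to 95475836), from 41.6 ± 5.3 to 1.07 ± 0.29 CPM, in FAM76A, from 6.70 ± 0.56 to 0.198 ± 0.16 CPM, in TRIM45, from 5.48 ± 0.70 to 0.196 ± 0.15 CPM, and in FBXO48, from 4.11 ± 0.70 to 0.163 ± 0.049 CPM. WNT9A (-4.61 ± 0.31), ANGPTL4 (-4.59 ± 0.16), PGM2L1 (-4.50 ± 0.22) and CBX7 (-4.47 ± 0.25) fell next. Of 20812 genes tested, 14599 changed, 6655 up and 7944 down, and 8256 of them by at least 2-fold (3629 up, 4627 down). The split depended on the scaling, with 7510 up and 7060 down with upper-quartile factors and 5579 up and 9098 down with library totals. All PdB libraries lay on the same side of all DMSO libraries in 72.5% of the genes tested, and in 96.6% of the changed genes, which were selected on the same libraries. Adjusted over the list alone, the counts differed in 6 lists: snoRNA hosts 17 up and 4 down, histones 5 and 0, homologous recombination 9 and 30, excision and mismatch repair 5 and 30, replication 4 and 39, and oxidative phosphorylation 39 and 10. The median change of all genes was -0.11 with TMM, -0.014 with RLE, 0.039 with upper-quartile factors and -0.31 with library totals, so changes are relative to that level. Without a spike-in, a change in the total RNA per cell was not measured.

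To ask whether the response followed gene structure, protein-coding genes were grouped by the introns of their longest annotated transcript. Under PdB the 517 genes without introns had a median log2 change of 0.70, with 57.4% rising and 17.6% falling. The 1594 genes with more than 20 introns had a median of -0.93, with 11.3% rising and 72.4% falling. The medians between these were 0.22 for 1-2 introns, 0.083 for 3-5 introns (-0.12 with library totals), -0.21 for 6-10 and -0.61 for 11-20. Genes without introns lay 0.96 above the 13696 others (camera p = 4.2e-10, p = 0.0021 with an estimated correlation), and across genes intron number and change had a Spearman rho of -0.32. The genomic span of a gene had a rho of -0.26 with the change under PdB. At recovery against DMSO rho was -0.21 for span and -0.18 for intron number. In the list of 48 single-exon genes fixed by name, of which 47 had no intron in the annotation, 37 rose and 7 fell (median log2 change 1.57, camera adjusted p = 1.2e-07, adjusted p = 0.30 with an estimated correlation). CEBPD, a transcription factor gene, rose from 4.82 ± 1.6 to 64.7 ± 5.2 CPM, and CLDN4, a claudin of tight junctions and the 1 member with an annotated intron, fell from 94.5 ± 11.8 to 17.1 ± 6.2 CPM. At recovery the difference from DMSO between genes without and with introns was 0.28 (camera p = 0.015, p = 0.090 with an estimated correlation). Between PdB and recovery the sign turned, with genes without introns 0.61 lower than the others (difference -0.61, camera p = 3.2e-06, p = 0.0084 with an estimated correlation). Genes are not independent replicates, and gene-level counts do not measure splicing.

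**Figure D3:**
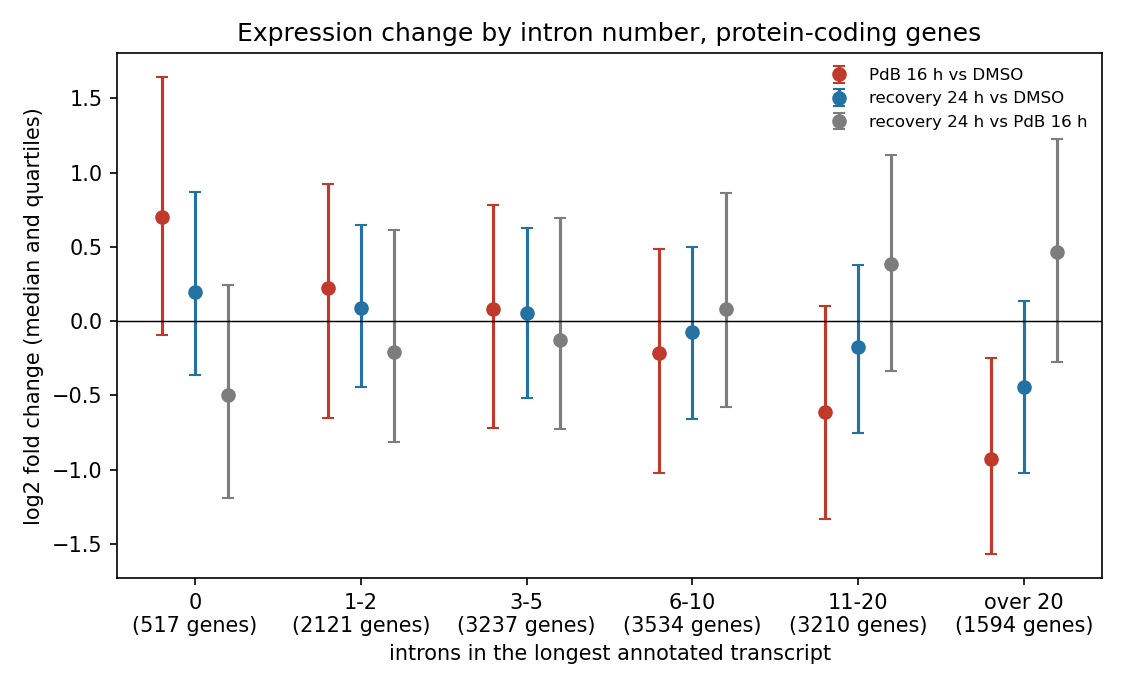
Median log2 change, with the interquartile range, of protein-coding genes grouped by intron number in the 3 comparisons. Under PdB the medians ran from 0.70 for genes without introns to -0.93 for genes with more than 20, and at recovery against DMSO from 0.20 to -0.44; with library totals the class of 3-5 introns lay at -0.12 instead of 0.083 under PdB, and at recovery against PdB the classes of 1-2 and 3-5 introns lay at 0.062 and 0.14 instead of -0.21 and -0.12. With upper-quartile factors the class of 6-10 introns lay at 0.00018 instead of -0.076 at recovery against DMSO.

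The comparison of recovery with DMSO asked what still differed 24 h after PdB. DNA replication genes were lower, with 5 of 45 up and 32 down (median log2 change -0.65, camera adjusted p = 1.3e-05, adjusted p = 0.36 with an estimated correlation). CDC45, a helicase subunit of the replication fork, was lower at recovery, from 53.3 ± 3.8 to 16.0 ± 0.97 CPM. E2F2 was still higher, at 24.6 ± 1.2 CPM. Of 44 homologous recombination genes, 10 rose and 25 fell (median log2 change -0.37, camera adjusted p = 0.021, adjusted p = 0.34 with an estimated correlation), and this call ended among genes with a mean of at least 50 counts (adjusted p = 0.089). BRCA1 stood at 43.3 ± 1.8 CPM (log2 change -0.40 ± 0.084, adjusted p = 0.00044), BRCA2 differed by -0.64 ± 0.12, and RAD51B fell from 4.47 ± 0.16 to 1.37 ± 0.20 CPM. PALB2 (0.20 ± 0.085, adjusted p = 0.051) did not pass the test. ATM and ATR were lower than in DMSO, with log2 changes of -1.11 ± 0.084 and -1.12 ± 0.087. Both also lay below their PdB levels, ATR by -0.55 ± 0.088. The ATM libraries held 27.3 to 30.8 CPM at recovery against 37.2 to 41.8 CPM in PdB. RNASEH2A was also lower than in DMSO (-1.26 ± 0.061), as was TOP2A, at 405 ± 7.4 CPM (-0.76 ± 0.045). FANCD2 differed by -0.27 ± 0.091 (adjusted p = 0.017), a call that ended without DMSO replicate 3 (adjusted p = 0.066) and without recovery replicate 2 (adjusted p = 0.057).

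The SF3B and U2 snRNP list and the snoRNA host list were higher at recovery. Of 20 genes of SF3B and the U2 snRNP, 16 rose and 2 fell (median log2 change 0.50, camera adjusted p = 0.00069, adjusted p = 0.50 with an estimated correlation). SF3B4 rose from 118 ± 3.8 to 318 ± 9.3 CPM, SF3B1 stood at 389 ± 11.5 CPM (0.59 ± 0.042), and DDX46, a helicase that works with the U2 snRNP, fell, with a log2 change of -1.54 ± 0.051. Of 22 snoRNA host genes, 18 rose and 0 fell (median log2 change 1.03, camera adjusted p = 6.9e-06, adjusted p = 0.48 with an estimated correlation), with SNHG17 at 3.68 ± 0.11 and GAS5 at 1.20 ± 0.068. Of 30 immediate early genes, 19 rose and 4 fell (median log2 change 0.74, camera adjusted p = 0.0014, adjusted p = 0.34 with an estimated correlation). NR4A3 rose from 0.444 ± 0.18 to 3.38 ± 0.42 CPM, ATF3 by 2.89 ± 0.087 and FOS by 1.35 ± 0.14. Of 15 mitochondrially encoded genes, 13 rose and 0 fell (median log2 change 0.54, camera adjusted p = 0.0012, adjusted p = 0.63 with an estimated correlation), with MT-RNR1 at 1.94 ± 0.050. Mesenchymal markers were lower, with 6 of 23 up and 16 down (median log2 change -0.72, camera adjusted p = 0.012, adjusted p = 0.52 with an estimated correlation). COL5A1, a fibrillar collagen gene, fell from 176 ± 24.8 to 29.2 ± 7.7 CPM and VIM, the intermediate filament of mesenchymal cells, from 2871 ± 51.9 to 1094 ± 13.4 CPM, whereas SNAI1, a repressor of E-cadherin, rose from 0.822 ± 0.16 to 8.45 ± 0.47 CPM. Of 20 drug transport and chemotherapy genes, 4 rose and 13 fell (median log2 change -0.62, camera adjusted p = 0.048, adjusted p = 0.34 with an estimated correlation). This last call ended with upper-quartile factors (adjusted p = 0.051), among genes with a mean of at least 50 counts (0.13) and with only these 6 libraries in the fit (0.053). ABCC4, an efflux transporter, fell from 53.5 ± 6.5 to 14.2 ± 1.3 CPM.

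The other 23 lists were not called at recovery, with camera adjusted p from 0.051 to 0.96. The 36 genes of G2 and mitosis were split, 13 up and 15 down, with KIF2C at 0.38 ± 0.065 and HMMR at -1.24 ± 0.13. CDKN1A, which fell under PdB, was above DMSO at 60.9 ± 4.6 CPM (0.56 ± 0.089). Of 78 ribosomal protein genes, 44 rose and 10 fell, and of 56 oxidative phosphorylation genes 14 rose and 24 fell. Of 23 SR genes 11 rose and 9 fell, with CLK3 at 1.53 ± 0.070 and SRSF2 at -1.13 ± 0.048. IL6 and CXCL8, secreted inflammatory cytokines, were higher by 2.38 ± 0.18 and 1.75 ± 0.19. HSPA5 stood at 559 ± 9.2 CPM (-0.36 ± 0.048), MYC at 195 ± 13.7 (0.10 ± 0.051) and BCL2L1 at 347 ± 4.4 (-0.79 ± 0.040). GAPDH and ACTB, used as reference genes in many assays, differed by -0.72 ± 0.036 and -0.42 ± 0.034 at recovery. Under PdB they had differed by 0.36 ± 0.036 and 0.18 ± 0.034, and ACTB lay at -0.015 there with library totals. Medians, means and tests pointed different ways in 4 lists: end joining (0.016, mean -0.26, test down), BCL2 family (-0.35, 0.075, down), luminal markers (-0.10, 0.25, up) and leukocyte markers (-0.28, 0.11, down). The median of the R-loop list, -0.045, was 0.031 with upper-quartile factors and 0.026 with library totals, and that of oxidative phosphorylation, -0.065, was 0.012 with upper-quartile factors and 0.0064 with library totals.

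Among the 8 largest rises at recovery, ranked in the same way, were those of KRT4, a keratin of stratified epithelia (ENSG00000170477.13, chromosome 12, 52806549 to 52814551), from 0.0386 ± 0.055 to 9.92 ± 2.3 CPM, and of PYGM, muscle glycogen phosphorylase, from 0.101 ± 0.077 to 16.4 ± 2.6 CPM. RNF225 stood at 4.65 ± 1.3 CPM and SNORA68 at 16.3 ± 1.7 CPM. SNORD3B-2, a copy of U3 RNA that shares reads with its other copies, was counted at 9.03 ± 1.0 CPM and is uncertain. The largest falls among the genes ranked were in CDK15, from 9.51 ± 1.4 to 0.582 ± 0.11 CPM, in the non-coding MANCR, from 33.5 ± 3.3 to 2.27 ± 0.13 CPM, in CDH4, a cadherin gene (ENSG00000179242.16, chromosome 20, 61252426 to 61940617), from 129 ± 14.4 to 9.61 ± 1.6 CPM, and in PLXNA4, a semaphorin receptor, from 10.1 ± 1.5 to 0.810 ± 0.19 CPM. SEMA3E (-3.56 ± 0.26), DZIP3 (-3.55 ± 0.19), CPS1 (-3.53 ± 0.40) and EPHB2 (-3.52 ± 0.13) followed. Of 20812 genes, 12746 changed, 6390 up and 6356 down, and 5279 by at least 2-fold (2824 up, 2455 down). All recovery libraries lay on the same side of all DMSO libraries in 70.4% of the genes tested and in 98.5% of the changed genes. Adjusted over the list alone, the counts differed for other core spliceosome (22 up, 13 down), hnRNP (9, 14), single-exon (21, 13), histones (6, 0), homologous recombination (11, 28), excision and mismatch repair (11, 21), ribosomal (45, 10), oxidative phosphorylation (15, 24) and mitochondrial genes (14, 0). The labels do not say when the DMSO cells were collected, so 24 h of further growth is part of this comparison if they were collected at the end of treatment. If they were collected with the recovery cells, such growth is part of the comparison of PdB with DMSO instead.

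The direct comparison of recovery with PdB asked what moved after the drug period. The recovery cells were collected 24 h after PdB, so further time in culture cannot be told apart from removal of the drug here. Genes of mitosis rose. Of 36 genes of G2 and mitosis, 30 rose and 2 fell (median log2 change 1.56, camera adjusted p = 2.7e-09, adjusted p = 0.34 with an estimated correlation). KIF2C rose from 8.91 ± 1.3 to 189 ± 3.9 CPM, a log2 change of 4.41 ± 0.080, and TOP2A from 35.2 ± 0.12 to 405 ± 7.4 CPM. BIRC5, the survivin gene, fell by 0.64 ± 0.050. Of 45 replication genes, 28 rose and 13 fell (median log2 change 0.80, camera adjusted p = 0.018, adjusted p = 0.58 with an estimated correlation), with RFC4, a clamp loader subunit, at 3.30 ± 0.11. Of 24 checkpoint genes, 16 rose and 4 fell (median log2 change 0.36, camera adjusted p = 0.0071, adjusted p = 0.34 with an estimated correlation), and CDC25C rose from 3.34 ± 0.20 to 15.3 ± 0.85 CPM. BRCA1 rose by 2.32 ± 0.093, yet the homologous recombination list, with 21 up and 14 down, was not called (camera adjusted p = 0.33). BABAM2, of the BRCA1-A complex, fell from 16.7 ± 2.2 to 7.32 ± 1.2 CPM. CDKN1A rose from 6.41 ± 0.48 to 60.9 ± 4.6 CPM.

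Several lists called up under PdB were called down after it. Of 78 ribosomal protein genes, 0 rose and 74 fell (median log2 change -0.59, camera adjusted p = 3.4e-13, adjusted p = 0.58 with an estimated correlation), with RPL30 at -1.29 ± 0.060. Of 56 oxidative phosphorylation genes, 6 rose and 49 fell (median log2 change -0.48, camera adjusted p = 3.4e-07, adjusted p = 0.58 with an estimated correlation), and of 48 single-exon genes 3 rose and 34 fell (median log2 change -1.04, camera adjusted p = 7.5e-08, adjusted p = 0.30 with an estimated correlation). Of 23 SR genes, 4 rose and 16 fell (median log2 change -0.72, camera adjusted p = 0.00089, adjusted p = 0.37 with an estimated correlation), among them SRSF2, which fell from 833 ± 42.7 to 111 ± 2.3 CPM. Of 26 unfolded protein and stress response genes, 9 rose and 16 fell (median log2 change -0.59, camera adjusted p = 0.030, adjusted p = 0.48 with an estimated correlation), and HSPA5 fell from 6053 ± 468 to 559 ± 9.2 CPM. This call ended among genes with a mean of at least 50 counts (adjusted p = 0.089) and with the replicate number as a block. Of 23 mesenchymal markers, which had no list call under PdB, 6 rose and 15 fell (median log2 change -0.71, camera adjusted p = 0.022, adjusted p = 0.55 with an estimated correlation), with SNAI2 at -2.92 ± 0.081, and this call ended at the same minimum of counts (adjusted p = 0.075). BCL2L1 fell from 1474 ± 42.9 to 347 ± 4.4 CPM and SLFN11 from 10.4 ± 0.51 to 0.416 ± 0.015 CPM. The other 22 lists were not called (camera adjusted p from 0.060 to 0.87). In the SF3B and other core spliceosome lists the medians (-0.034 and -0.025, or 0.23 and 0.24 with library totals) and the means (0.043 and 0.11) differed in sign, as they did for cholesterol synthesis (-0.22 and 0.037), and camera's direction was down in all 3. Among the 8 largest rises, ranked as above, were those of SYT17, from 0.104 ± 0.060 to 4.07 ± 0.16 CPM, of CCNA1, a cyclin, from 1.02 ± 0.45 to 22.8 ± 2.2 CPM, and of PIF1, a DNA helicase, from 1.59 ± 0.095 to 30.9 ± 2.0 CPM, with SPTB at 4.28 ± 0.34. Among the 8 largest falls were those of CCDC181, from 6.44 ± 0.35 to 0.0730 ± 0.020 CPM, of SELPLG, from 69.3 ± 10.2 to 3.04 ± 0.27 CPM, of FGF18, from 18.2 ± 1.5 to 1.25 ± 0.080 CPM, of OVGP1, from 52.8 ± 6.3 to 3.67 ± 0.83 CPM, and of MINAR1 (-4.07 ± 0.28).

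Of 20812 genes, 13767 changed between PdB and recovery, 7204 up and 6563 down (52.3% up), and 6844 by at least 2-fold (4092 up, 2752 down). All libraries of the groups were separated in 70.5% of the genes tested and in 97.4% of the changed genes. With upper-quartile factors the split was 6768 up and 7021 down, and with library totals 8862 up and 4876 down (64.5% up). The median change of all genes moved from 0.062 to 0.33 with library totals, and under it the medians of the histone, BCL2, hnRNP, immediate early, cholesterol and mitochondrial lists turned from negative to 0.13, 0.022, 0.059, 0.21, 0.051 and 0.15. Those of the Fanconi and NF-kB lists, 0.017 and 0.0018, were -0.056 and -0.072 with upper-quartile factors. Adjusted over the list alone, the counts differed for single-exon genes (3 up, 35 down), histones (3, 2), homologous recombination (22, 14), excision and mismatch repair (24, 9), ribosomal (0, 75), mesenchymal (7, 16) and drug response genes (5, 14).

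To describe reversibility, each of the 14599 genes changed under PdB was sorted by its state at recovery. All the classes rest on 1 DMSO group of unstated collection time. Time in culture may therefore be part of them and was not separated from removal of PdB. For 3424 genes (23.5%) the level moved back at the threshold and no longer differed from DMSO at it, among them PHF5A, PGM2L1 and TRIM45. A change of the same sign persisted for 8096 genes (55.5%), 3899 up and 4197 down, among them SF3B1, BRCA1, ATM and TOP2A. An overshoot past DMSO was found for 2363 genes (16.2%), among them CDKN1A, KIF2C and HSPA5, and 716 (4.90%) were undetermined. With 2-fold changes required in both comparisons, 2874 of 8256 genes persisted and 161 (1.95%) overshot, and CDKN1A, KIF2C and HSPA5 were not among the latter, with changes from DMSO of 0.56 ± 0.089, 0.38 ± 0.065 and -0.36 ± 0.048 at recovery. Among the persistent genes, 5260 (65.0%) had a smaller change at recovery, and the median absolute log2 change went from 1.26 under PdB to 0.93. Between PdB and recovery, 3919 of them moved toward DMSO at the threshold, BRCA1 and TOP2A among these, and 1677 moved further away. Of 44 homologous recombination genes 27 persisted and 7 returned, of 36 G2 and mitosis genes 15 persisted, 13 overshot and 7 returned, and of 78 ribosomal protein genes 44 persisted and 24 returned. A further 2287 genes passed the test at recovery but not under PdB (1151 up, 1136 down) with SPTB, an erythrocyte spectrin gene, among the rises. Both comparisons share the DMSO libraries. Their log2 changes correlated across genes with Pearson r = 0.58 and Spearman rho = 0.51, against r = 0.49 (highest 0.51) in 20 simulations of unchanged groups. The observed r was 0.50 without a filter and 0.52 without PdB replicate 3, near that highest value, but no simulation was run for these settings. The covariance was 1.25 against 0.095 simulated, a difference of 1.16. The changes had the same sign in 68.1% of genes, against 66.7% simulated. In unchanged groups r and the share of same signs come from the shared DMSO libraries alone, however small the noise. They are therefore no baseline for groups that differ, and do not show how far the changes agree. The simulations gave at most 0 persistent genes, and independent lists of the same lengths would share 2043 genes up and 2426 down. The 3 DMSO libraries were not split, since 1 side would hold a single library, so part of the excess in correlation and in shared genes may come from the shared controls, which the difference in covariance leaves out.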

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

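All alternatives here were planned. The counts of changed genes kept within 1.5 times of the values reported in every alternative but the test against a 2-fold change (glmTreat), which gave 5989 genes for PdB against DMSO, 2903 for recovery against DMSO and 4451 for recovery against PdB, as a stricter null by construction. DESeq2 gave 14821, 13079 and 14016 genes, an FDR of 0.01 gave 12864, 10908 and 12001, and no filter gave 15005, 12903 and 14027 of 34154 genes. Leaving out 1 library at a time gave 14002 to 14762, 11715 to 13325 and 12931 to 14034 changed genes, 3262 to 3676 returned genes, 7522 to 8252 persistent genes, 31 to 34 called lists and a difference between genes without and with introns of 0.943 to 0.997. The correlation of the 2 changes against DMSO went from 0.58 to 0.50 without a filter, and ranged from 0.517 to 0.607 with 1 library left out. The cause was not tested. Of the 30 list calls, 0 held when camera estimated the correlation from the data, and fry, which does not compare a list with other genes, called 75. With the other alternatives the adjusted p of the called lists ran up to 0.13, for drug transport and chemotherapy genes at recovery. At an FDR of 0.01, 22 list calls held. Homologous recombination under PdB (camera adjusted p = 0.01009) was not among them.

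The replicate block gave 14628, 12922 and 13871 changed genes. The numbers were not taken to pair the libraries, because deviations of same-numbered libraries correlated by -0.0032 to 0.048, with 0 of 9 pairs above 0.1. Still, 5 of the 9 libraries correlated best with their own number in both other groups, where about 1 of 9 is expected by chance, a hint of pairing from the data and not from the design. The block ended the call of the stress response list at recovery against PdB (adjusted p = 0.050) and of H4C12 and SHLD1 there.

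Of all values of named genes under the alternatives, 10206 stayed on their side of the threshold (64 of these were uncalled values whose sign changed), 105 gained a call, 173 lost it and 11 reversed. For lists the counts were 1639 (26 uncalled), 78, 46 and 1. The reversed list was SF3B and U2 snRNP at recovery against PdB, which fry called up (adjusted p = 0.026) with a median of -0.034. With library totals, changes under PdB were -0.073 for DDX46, -0.17 for SHLD2, -0.12 for JUN and -0.015 for ACTB, and at recovery against PdB 0.25 for CDK1, 0.25 for SYF2, 0.26 for BOK, 0.0031 for MCL1, 0.25 for BARD1 and 0.24 for CHEK1. The cause was not tested, but this scaling moved the median of all genes from -0.11 to -0.31 and from 0.062 to 0.33. FAAP100 under PdB was at 0.0042 with upper-quartile factors, and the cause was not tested. Leaving out 1 library ended 28 calls of 26 named genes and no call of a list. Under PdB these were ATOH1, CDH2, DDX46, FAAP100, FAS, FOXA1, H4C11 and SHLD1. At recovery against DMSO they were APEX1, CCNB1, CSF2, FAAP20, FANCD2, FCER1G, OAS1, PARP14 and PARP2, and at recovery against PdB ABCC4, BMF, CCNB1, CD79A, H4C12, MT-RNR2, NDUFB9, NEIL3, PLXNA4, RN7SL146P and SHLD1.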

Other observations

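The patterns weighed here were noticed in these data. Outcomes were predicted before the results were seen for the explanations of intronic small RNA genes and for transcript length and GC content. The same holds for the homologous recombination list and for regroupings of the libraries. Comparisons of other lists with matched lists, of opposite-strand introns, and of snoRNA genes with hosts at recovery had no prediction and are descriptive. Genes for small RNAs inside introns formed a further group that rose. Small nucleolar RNA (snoRNA) genes, whose products guide chemical changes of ribosomal RNA and lack a poly(A) tail, held 0.0263% ± 0.0026 of all counts in DMSO, 0.121% ± 0.010 in PdB and 0.0899% ± 0.0020 at recovery (mean ± SD, n = 3). Of 185 snoRNA genes in an intron of a gene on the same strand, 141 rose and 4 fell under PdB (median log2 change 2.49, or 2.42 with genes absent from DMSO at their lower bound), and 134 rose and 2 fell at recovery against DMSO (1.97, or 1.96). Of 214 microRNA genes in such introns, 97 rose and 23 fell under PdB (median 1.15), and of 215 processed pseudogenes 94 rose and 17 fell (median 0.79). Processed pseudogenes outside any gene moved less, with 76 of 263 up and 23 down (median 0.53), and these share reads with their parent genes. The genes annotated as misc_RNA showed the opposite order under PdB, with a median of 1.51 for 71 in same-strand introns (31 up, 7 down) and 1.815 for 10 outside any gene (6 up, 0 down).

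Some lists lay far from other genes of like structure. Against 10000 lists matched on intron number and expression, the G2 and mitosis list under PdB (-1.54, matched median -0.12, 95% of draws from -0.47 to 0.25) and the DNA replication list (-1.17, matched median -0.24) lay below every draw. At recovery against DMSO the replication list was again below every draw (-0.65, matched median -0.088). Draws took genes singly and did not carry correlation between members, estimated at 0.22 for G2 and mitosis and 0.12 for replication. With an estimated correlation camera called neither list (adjusted p = 0.34 for both under PdB, 0.36 for replication at recovery). The single-exon list under PdB (1.57) was above every matched list (median 0.67). The Fanconi anaemia list lay in the middle of its draws under PdB (percentile 50.1). Called lists also lay within 95% of their draws: under PdB the DNA damage checkpoint list (-0.63 against -0.56, percentile 38.15), excision and mismatch repair (-0.84 against -0.50, percentile 5.19) and the ribosomal protein list (0.74 against 0.61, percentile 96.1), and at recovery against PdB the checkpoint list (0.36 against 0.29, percentile 60.2) and the ribosomal protein list (-0.59 against -0.61, percentile 56.6). Only the lists named here and homologous recombination were set against matched lists. Other called lists, such as the SR, stress response, immediate early, snoRNA host and oxidative phosphorylation lists, were not. Their changes were therefore not separated from the intron number of their members.

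The rise of intronic small RNA genes under PdB was set against 3 explanations. Higher host gene levels are argued against, because snoRNA genes rose by 2.22 more than their hosts (95% bootstrap interval 1.88 to 2.66, 119 hosts with a median change of 0.30), and by 1.84 more at recovery. The bootstrap intervals in this section resampled genes, not libraries, and so leave out the spread between libraries. The 185 snoRNA genes share these 119 hosts and are not independent, so their interval may be too narrow. Reads from introns kept in the host transcript are a candidate explanation: intronic snoRNA genes changed by 1.67 more than the 7 outside any gene, but the interval of -0.68 to 2.51 holds 0, and at recovery against DMSO the order was the opposite (median 2.87 for the 7, with 5 up and 0 down, against 1.97), so retained introns and a change in the snoRNAs themselves cannot be told apart. Pseudogene and microRNA genes in same-strand introns changed by 0.447 more than those outside any gene (0.16 to 0.67) and those in opposite-strand introns by -0.026, which may reflect reads from introns in general, yet an effect on snoRNA counts alone was not excluded for the snoRNA part. The sets differed in make-up, with 214 microRNA genes and 215 pseudogenes in same-strand introns but 11 and 263 outside any gene. Medians by type were 1.15 against 0.61 for microRNA genes and 0.79 against 0.53 for pseudogenes. Part of the pooled difference may therefore come from the mix of types. Treatment with PdB, the biological difference in the design, stays open, and gene-level counts do not separate introns from the RNAs within them.

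The higher level of genes with few introns was set against transcript length and GC content. After regression on length, GC content and expression, genes without introns still lay 0.942 above the others (95% bootstrap interval 0.79 to 1.08), against 0.959 before, which argues against these as the whole cause. This interval too came from resampling genes and leaves out the spread between libraries. The dependence of transcripts on splicing is a candidate explanation, as is a change in RNA stability or in cell state, and these were not tested apart. Neither the regression nor the matched lists took account of the genomic span of genes, so span was not separated from intron number.

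The fall of homologous recombination genes under PdB was set against their number of introns, with a median of 10 per gene against 7 for all protein-coding genes tested. The list's median of -0.86 stood at percentile 4.64 of matched lists (matched median -0.52, 95% of draws from -0.91 to -0.12), and at recovery its -0.37 stood at percentile 12 (matched median -0.20, from -0.49 to 0.083). Intron number is therefore a candidate explanation for both, since each median lay within the range of its draws. Fewer cells in S phase, G2 and mitosis could also lower these genes: the replication and mitosis lists fell with medians of -1.17 or below, and without a measure of cell cycle phase the 2 cannot be told apart. A specific effect on recombination genes was not separated from either.

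With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each case 1 of the 10, the real split, gave as large a value. The real splits gave 13875 changed genes for PdB against DMSO, 13595 for recovery against DMSO and 13410 for recovery against PdB when only those 6 libraries were fitted, and the highest of the other splits gave 0 in each. Every other split mixes libraries of both groups on each side, which widens the spread there. Its 0 is therefore not the level of false calls in unchanged groups. The difference between genes without and with introns was 0.977, and at most 0.349 in the other splits. Among 100 assignments of the 9 libraries to 3 groups, the real one included, 3 gave as many returned genes as the 3424 seen (highest other 6748) and 1 gave as many persistent genes as the 8096 seen (highest other 6748), so a random grouping of the libraries is excluded for both at a share of 0.05. Of the 99 other assignments 95 gave 0 genes of either kind, so these shares show that the groups differ and do not bear on return or persistence as such. For the number of called lists, 30 of the 100 gave at least the real 30 (highest other 41), and for the correlation of the changes 43 gave at least the real 0.58 (highest other 0.933). These shares do not exclude a random grouping, but assignments that mix libraries of different groups carry the differences between the groups into both changes, so they do not bear on what the correlation would be without any change. In the simulations of unchanged groups the highest r was 0.51 and the covariance 0.095, against the 0.58 and 1.25 seen. The r seen was 0.50 without a filter and 0.52 without PdB replicate 3, settings for which no simulation was run. The simulated r comes from the shared DMSO libraries alone, however small the noise. The comparison of r therefore does not show how far the changes agree.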
